A study of Drosophila melanogaster with 24 samples.

How the data were processed

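Transcript levels were measured by RNA sequencing in brains dissected by hand from adult female flies of 2 genotypes, wildtype and per0, a null allele of the clock gene period. Per the labels the flies were kept at 25 degrees in constant darkness, and 1 library per genotype was made every 4 h from CT24 to CT68, which gave 12 libraries per genotype and 24 in all. All 24 libraries carry the same labels for strain, kit and read layout: amplified RNA made with a kit that does not rely on polyA tails, and paired reads. No batch or date is labelled, so no value within batches can be given, and the strain label is Canton S for both genotypes.

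The deposited table gives RPKM, reads scaled to feature length in kilobases and to mapped reads, computed by the authors for 43331 transcripts, 252461 exons and 209130 introns. Counts of reads per splice junction are deposited for each library as whole numbers without normalization. The aligner named in the table and in the junction headers is RUM; its version, the genome build and the settings behind the deposited values are not given in the sources used here. Coordinates are those of the deposited files, and reference tables served for current gene symbols alone, which 8885 of the tested labels matched uniquely. Another 1064 tested labels are unnamed transcribed regions of the authors' annotation.

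Every RPKM value was checked to be a whole multiple of a step set by feature length and library, which held for 100% of exon and intron values and 100% of transcript values in each library. That step gave the mapped reads behind the normalization: 6.84 to 14.1 M per library (M, 1e6 reads), with a median of 10.6 M. Such recovered reads were used for counting intervals, which are exact and at 95%, for a floor of 3 reads over a genotype where no read was seen, and for 1 alternative fit. Intervals and floors cover counting error only.

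The transcript with the highest mean represented each of 17020 gene labels. Genes with at least 1 RPKM in at least 6 libraries were tested (10423), and 6597 were left out. Values were analysed as log2 of RPKM plus 0.1 with limma 3.58.1 in R 4.3.3, with a mean trend in the prior. A single fit over 24 libraries held the mean of each genotype and a cosine and sine of a 24 h cycle for each genotype. From it came the genotype effect, the rhythm in wildtype, the rhythm in per0 and the difference in rhythm; a term for the second against the first day was added for the day effect. P values were adjusted by Benjamini and Hochberg over all tested genes with a threshold of 0.05. The peak to trough size is double the fitted amplitude. The deposited scale put the median gene at -0.16 (log2, per0 minus wildtype), against -0.03 after a median-of-ratios scaling, so log2 changes between genotypes are given relative to the median gene, while calls come from the deposited scale. Levels are means with their SD over 12 libraries of a genotype, which include time of day.

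Junction usage was the share of a junction among all junctions with the same left or right splice site, because strand is not given in the junction files. Sites with at least 10 reads in at least 18 libraries and junctions with a pooled share of 5 to 95% were tested, 3489 in all, by quasi-binomial regression with an F test. These lie at 1597 sites in 835 gene labels, and the 2 shares of a site with a pair of junctions are complements, so calls come in pairs.

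The 25 gene lists were fixed before any value was seen; 24 had measured genes, and the transposon list had 0. Lists were tested in the genotype effect with limma's camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry, which tests whether the genes of a list move one way on balance and does not compare them with other genes. Fry was run on the deposited scale, so its p values include the offset of the median gene at -0.16. In the wildtype rhythm they were tested with a two-sided Fisher's exact test of members at unadjusted p under 0.05. The ribosomal protein and snoRNA lists share 32 genes, the output and retina lists share 2, and 5 members of the nuclear oxidative phosphorylation list lie on the mitochondrial chromosome. Outputs share 1 gene each with the fat body, detoxification and sleep lists, and neuron markers share 1 each with the spliceosome and sleep lists.

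Genes were named by a rule fixed before any value was seen: every core clock gene; the 12 highest and 12 lowest log2 changes among genes past the threshold for genotype; the 12 smallest p values for the wildtype rhythm, since fewer than 10 genes passed; the 10 smallest for each of the per0 rhythm and the rhythm difference; up to 4 members of each list by p; and the 8 smallest p values in each junction comparison. The rule also provided for 6 genes each way in the day effect, where none passed.

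Alternatives fixed beforehand were other pseudocounts (0.01 and 1), filters (none, or 5 RPKM), scalings (median of ratios, quantile), a threshold of 0.1, every transcript, time point as a factor, no time terms, each day alone, wildtype fitted alone, a Kendall rank test against cosine curves with an exact null, a peak to trough minimum of 1.5-fold, periods of 20 and 28 h, a day term, other junction filters and an arcsine model, and each library left out in turn. Chosen after seeing the data were edgeR 4.0.16 (quasi-likelihood, TMM) on the recovered reads, leaving out per0 CT60 and CT68, leaving out the most used junction of each site, and a junction dispersion not under 1. DESeq2 was to be used only if the table held counts, and was not run. Data were handled with the R package data.table (version 1.17.8), Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and plots were drawn with matplotlib 3.10.9.

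The fits were tested on simulated data with 200 changed genes. Gene values were drawn independently for each library around the gene's mean with its residual SD, without variation shared by the genes of a library. Recovery and false calls in the real data, where libraries such as per0 CT60 and CT68 stand apart, may therefore differ. The genotype fit recovered 43% of changes of 0.5 and 76% of changes of 1 (log2), with 9 false calls among 10223 unchanged genes. Wildtype rhythms with a peak to trough of 1 or 2 (log2) were recovered in 36% and 72% of genes by limma, and in 8% and 26% by the Kendall test. Recovery was 32% and 70% for per0 rhythms, 9% and 37% for rhythm differences, and 47% and 78% for day effects of 0.5 and 1. For junctions, 35 of 100 shifts of 0.1 and 70 of 100 shifts of 0.2 in the share were recovered, with 4 false calls among 3289.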

Results

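The data describe transcript levels in fly brains over 2 days of constant darkness, in wildtype flies with a working circadian clock and in per0 flies, which lack functional Period protein. Each genotype had 12 libraries, 1 per time point, so that each of 6 circadian phases was sampled on 2 successive days. Mapped reads came to 10.0 ± 1.38 M per wildtype library and 11.6 ± 1.62 M per per0 library (SD, n = 12). Between 435013 and 912006 reads per library spanned splice junctions, at 31040 to 47165 junctions. The labels describe separate time points rather than independent cultures of flies, so p values measure the spread between these libraries.

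The largest axis of variation, with 26.4% of the variance, separated the genotypes. The second, with 13.3%, separated per0 CT60 and per0 CT68, at scores of -73.8 and -69.2, from all other libraries. Those libraries had the fewest junctions, 32065 and 31040. Transcripts under 100 nt with at least 1 read numbered 151 and 123 in them, of 564, against 192 to 228 in the other per0 libraries. Mitochondrial large ribosomal RNA (mt:lrRNA) stood at 95.3 and 97.4 RPKM there, against 243.9 ± 85.3 in the other 10 per0 libraries. The most abundant transcript, CR40642, an RNA of the unplaced sequence U, took 16.9% ± 3.07 of reads in wildtype and 7.52% ± 2.74 in per0 (SD, n = 12).

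**Figure D1:**
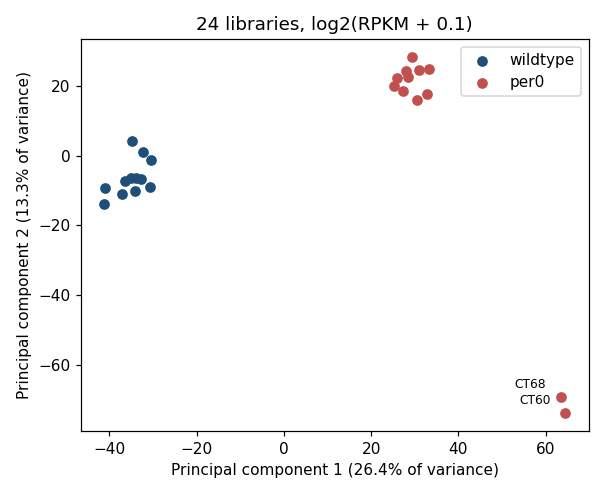
Each point is 1 library, placed by its scores on the first (26.4% of variance, horizontal) and second (13.3%, vertical) principal component of log2 RPKM, without units and coloured by genotype. Genotypes separate along the first component, and per0 CT60 and CT68 lie at -73.8 and -69.2 on the second.

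The genotype comparison asked which brain transcripts differ when the clock lacks Period. All 8 core clock genes differed, 6 upward and 2 downward. timeless (tim, 2L:3493986-3503814), whose protein is the partner of Period in repressing transcription, rose from 58.7 ± 22.3 RPKM in wildtype to 136 ± 17.0 in per0 (SD, n = 12 each), a log2 change of 1.48 ± 0.11 (SE, adjusted p = 1.11e-08), and every per0 library lay above every wildtype library. Clock (Clk, 3L:7757071-7768703), the activator of per and tim, fell from 7.92 ± 3.20 to 2.11 ± 0.468 RPKM (log2 -1.64 ± 0.13, adjusted p = 1.1e-09), with all 12 per0 libraries below every wildtype library.

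The direct targets of the activator followed tim in direction. vrille (vri, a repressor of Clk) rose from 11.9 ± 4.20 to 20.6 ± 3.38 RPKM (log2 1.02), and Pdp1, which encodes an activator of Clk, from 58.0 ± 15.3 to 83.1 ± 11.2 (log2 0.71). per RNA itself rose from 2.07 ± 0.902 to 3.77 ± 1.05 RPKM (log2 1.07, adjusted p = 6.8e-05); the allele carries a nonsense mutation. clockwork orange (cwo), a repressor, rose by 0.46 (log2), and cycle (cyc), the partner of Clk, by 0.63. The blue-light receptor cryptochrome (cry) fell from 1.75 ± 0.736 to 0.909 ± 0.277 RPKM (log2 -0.67). Each of per, tim, cyc, vri, Pdp1 and cwo lay above the wildtype mean in 12 of 12 per0 libraries, and Clk and cry lay below it in 12 of 12. The core clock list moved upward by camera (adjusted p = 0.0199), and adjusted p = 0.258 with an estimated correlation.

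**Figure D2:**
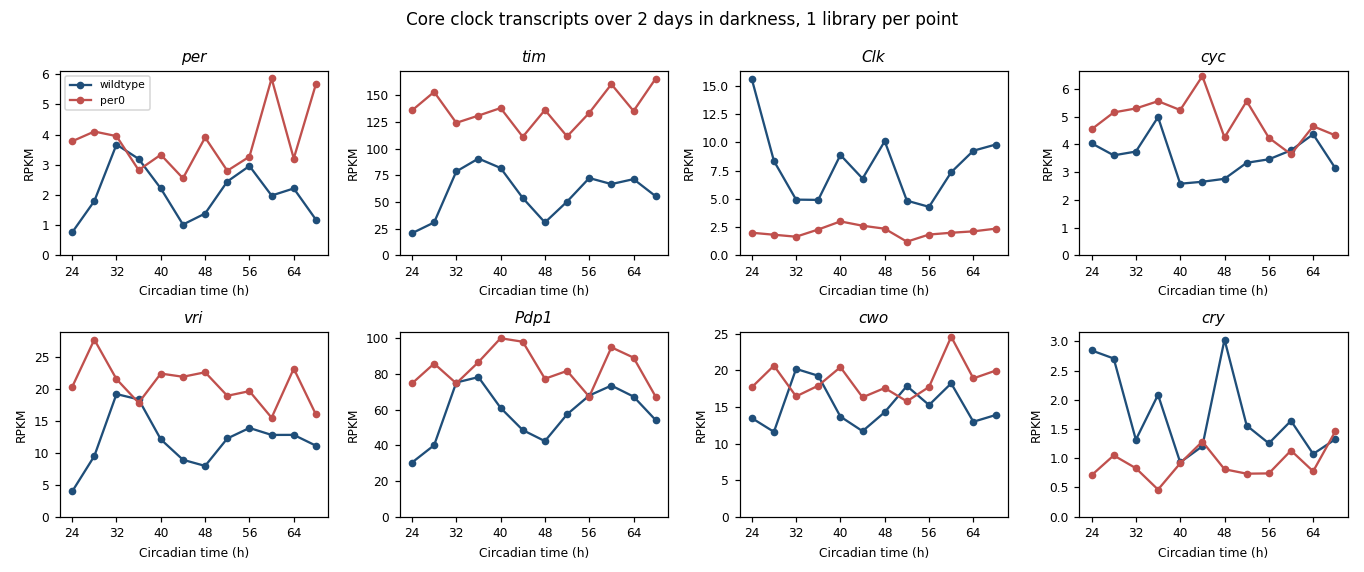
RPKM (vertical) of the 8 core clock genes against circadian time in hours (horizontal), where each point is 1 library and lines join the libraries of a genotype. Wildtype tim goes from 20.8 RPKM at CT24 to 90.8 at CT36 while per0 stays between 111 and 166, and Clk in per0 lies below every wildtype library.

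In the transcriptome as a whole, 4024 of 10423 genes differed (38.6%; limma, 4891 at unadjusted p under 0.05), 1187 upward and 2837 downward on the deposited scale. The balance depended on scaling: after median-of-ratios scaling 3663 differed, 1815 upward and 1848 downward. With the same sign under both scalings, 1187 rose and 1848 fell. At least a 2-fold change relative to the median gene was seen in 718, with 309 higher and 409 lower. With 12 libraries in place of 24, the first day alone gave 2934 genes and the second day, which holds per0 CT60 and CT68, gave 1267.

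Among the 12 largest increases were genes nearly silent in wildtype. mthl8 (3L:22702-26316), which encodes a receptor of the Methuselah family, went from 0.0227 ± 0.0287 to 6.82 ± 0.855 RPKM (adjusted p = 2.6e-18). The C-type lectin gene lectin-28C went from 0.373 ± 0.277 to 13 ± 5.21 RPKM (log2 5.14). Chemoreceptor genes were present too, with log2 changes of 4.61 for the odorant receptor Or45b and 4.03 for the gustatory receptor Gr65a; CG34284 changed by 4.44. The highest was an unnamed region at U:7356781-7357351, which went from 1.93 ± 0.659 to 170 ± 30.3 RPKM (log2 6.60, adjusted p = 1.31e-18), and the noncoding regions nc_14317 and nc_17701 rose by 5.30 and 3.87. An unnamed region at 2L:17584687-17585177 rose by 3.91. Few reads underlie the others: mir-184S had 1 read in wildtype and 22 in per0 (ratio 19.0, 95% interval 3.07 to 785), mir-9a had 2 and 12 (5.19, 1.15 to 47.7), and a region at 2R:11259541-11259772 had 0 and 77, which is at least 22.2-fold. Apart from mir-184S (8 of 12), mir-9a (9) and that region (10), all per0 libraries lay above the wildtype mean.

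The 12 largest decreases included transcripts almost lost from per0. Overlapping noncoding regions on chromosome 4, which can share reads, went from 94.5 ± 19.9 to 0.185 ± 0.405 RPKM for nc_20981 (4:1337613-1351287; log2 -8.99, adjusted p = 3.93e-14) and from 200 ± 26.4 to 1.66 ± 0.960 for nc_20983 (log2 -6.85). In the same stretch nc_20985 changed by -8.76 and nc_20982 by -7.74. Elsewhere nc_21062 changed by -7.05 and nc_3949 by -4.40. Unnamed regions on sequence U changed by -7.35 and -5.29, and a transcript model on 2L by -4.44. Of the protein-coding genes, CG11697 had 874 reads in wildtype and 1 in per0, a ratio of 1011 (95% interval 181 to 39990), CG8757 went from 4.85 to 0.0502 RPKM (log2 -4.97), and CG9377 from 10.6 ± 6.05 to 0.398 ± 0.257 (log2 -4.19). In all 12 the decrease held in 12 of 12 per0 libraries.

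Of 79 ribosomal protein genes 52 fell and 0 rose, and 55 fell adjusted over the list alone; 45 fell after median-of-ratios scaling, and under quantile scaling 52 fell and 1 rose. RpL24 fell from 49.9 ± 10.6 to 21.4 ± 3.59 RPKM (log2 -1.05, adjusted p = 3.28e-08), RpS26 from 31.1 to 12.3 (log2 -1.18), RpS20 from 39.5 to 18.7 (log2 -0.93) and RpS6 from 18.7 to 9.32 (log2 -0.84). The list median was -0.45. Camera gave adjusted p = 1.41e-08, and adjusted p = 0.902 with an estimated correlation, while fry gave 2.29e-04. snoRNAs and their host genes split, with 13 up and 43 down of 226, and 12 and 41 adjusted over the list alone. That list holds 32 ribosomal protein genes, 22 of them down, and the other 194 members gave 13 up and 21 down, or 25 and 24 without per0 CT60 and CT68. snoRNA:Psi18S-1377e rose from 8.39 to 55.8 RPKM (log2 3.04), snoRNA:Psi18S-1377d from 8.69 to 36.5 (log2 2.26), and snoRNA:Psi28S-3436a fell from 32.3 to 5.92 (log2 -2.36). In per0 CT60 and CT68 the snoRNA list had medians of -0.93 and -0.84 against the other per0 libraries. Spliceosome and RNA-processing genes gave 3 up and 6 down of 21, which turned to 7 up and 3 down after rescaling; squid (sqd), an RNA-binding protein, rose from 119 to 234 RPKM (log2 1.12), and the splicing factor subunit U2af38 fell from 8.73 to 4.21 (log2 -0.87), with Srp54 at -0.62 and Rbp9 at -0.30. For this and the following lists, counts adjusted over the list alone were the same as over all genes unless another number is given.

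Immune and stress lists had more members down than up on the deposited scale. Antimicrobial and immune genes gave 3 up and 13 down of 22, and 4 and 13 adjusted over the list alone, with the same 13 down after rescaling; the 3 that rose, chosen here after their values were seen, were IM2, IM4 and IM14. The stress-induced Turandot genes TotA and TotC changed from 17.9 ± 13.5 to 2.48 ± 2.67 RPKM (log2 -2.79) and from 9.95 to 1.14 (log2 -3.12), PGRP-LF, of the peptidoglycan recognition protein family, from 3.67 to 1.14 (log2 -1.46) and the immune-induced peptide IM10 from 17.9 to 6.10 (log2 -1.42). Camera gave adjusted p = 0.183, adjusted p = 0.902 with an estimated correlation, and fry 0.00949. Heat shock genes gave 3 up and 7 down of 20, and 3 and 8 adjusted over the list alone; the co-chaperone starvin (stv) rose from 16.5 to 30.8 RPKM (log2 1.05), the small heat shock gene Hsp22 from 0.235 to 3.94 (log2 3.74), and Hsp83 fell from 93.0 to 59.9 (log2 -0.49). Their median was -0.11 and their mean 0.19 (camera adjusted p = 0.681). Of the 3 entries that rose, only stv does not cover Hsp22, since a joint label of Hsp22 with Hsp67Bb (log2 3.07) was counted beside Hsp22 itself. In per0 CT60 and CT68 this list had medians of 0.55 and 0.62 against the other per0 libraries, and without them 13 members fell, while 4 fell under quantile scaling. Detoxification genes gave 4 up and 7 down of 27 (adjusted p = 0.681 by camera, 0.902 with an estimated correlation and 0.025 by fry), with a median of -0.06: the cytochromes P450 Cyp6a2 and Cyp28d1 fell from 6.83 to 1.34 (log2 -2.20) and from 136 to 53.1 RPKM (log2 -1.18), the glutathione transferase GstE1 rose from 2.54 to 6.61 (log2 1.46), and GstD9 changed by -1.61. On the deposited scale, which fry used, the detoxification median was -0.21.

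Neuronal and glial genes moved in both directions. Neuron markers gave 6 up and 1 down of 15: the synaptic vesicle genes n-syb and Syt1 rose from 554 to 783 (log2 0.65) and from 359 to 477 RPKM (log2 0.56), the active zone gene bruchpilot (brp) from 101 to 135 (log2 0.55), and the glutamate transporter VGlut fell from 34.2 to 20.5 (log2 -0.61). Camera gave adjusted p = 0.0668, and adjusted p = 0.902 with an estimated correlation. Neuropeptide genes gave 3 up and 11 down of 25, 3 and 13 adjusted over the list alone, 3 and 8 after rescaling, and 2 and 14 without per0 CT60 and CT68. Among those that fell were the insulin-like peptide genes Ilp2, from 59.3 to 36.9 RPKM (log2 -0.51), and Ilp3, from 65.2 to 31.0 (log2 -0.90), and neuropeptide F (npf), from 29.8 to 14.2 (log2 -0.89), whereas capa rose from 6.14 to 12.5 (log2 1.15). Camera gave adjusted p = 0.544, adjusted p = 0.902 with an estimated correlation, and fry 0.00303. Peptide and amine receptors gave 1 up and 4 down of 14, 3 and 4 adjusted over the list alone, the reverse balance of 4 up and 1 down after rescaling, and 0 up and 5 down without per0 CT60 and CT68. The diuretic hormone receptor Dh44-R1 stood at -0.46, with DopR at -0.18, 5-HT2 at -0.17 and Oamb at -0.16, and these last 3 calls were lost under other scalings. Glia markers gave 4 up and 3 down of 9, with the glutamate transporter Eaat1 from 38.9 to 58.3 RPKM (log2 0.73), glutamine synthetase Gs2 from 161 to 239 (log2 0.71), anachronism (ana) at 0.88 and wrapper at -0.48. Activity-dependent early genes gave 3 up and 1 down of 10, or 4 and 2 without per0 CT60 and CT68, with puc at 0.64, CG8910 at 0.79, stripe (sr) at 0.99 and cbt at -0.45. Sleep genes gave 1 up and 2 down of 6, or 3 and 2 after rescaling, with quiver (qvr) from 170 to 216 RPKM (log2 0.48), the channel gene Shal at -0.43 and cv-c at -0.21.

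Clock kinases and output genes were split. Of 11 kinase, phosphatase and degradation genes 2 rose and 1 fell, or 4 and 1 after rescaling: casein kinase 2 alpha (CkIIalpha) fell from 78.2 to 45.3 RPKM (log2 -0.66, adjusted p = 3.67e-06), shaggy (sgg) rose from 115 to 150 (log2 0.54) and CkIalpha from 75.7 to 94.8 (log2 0.48), while mts, at 304 and 388 RPKM, did not pass (adjusted p = 0.081). Clock-controlled output genes gave 5 up and 4 down of 17, with ebony (e), an enzyme of amine metabolism, from 7.68 to 4.64 RPKM (log2 -0.57), CG10553 from 17.6 to 27.1 (log2 0.82), and Cyp18a1 from 2.72 to 1.52 (log2 -0.65).

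Markers of tissues next to the brain also differed. Retina markers, present in both genotypes, gave 3 up and 9 down of 22, or 6 and 7 after rescaling; the phototransduction channel gene trpl fell from 216 ± 45.9 to 43.9 ± 6.62 RPKM (log2 -2.12, adjusted p = 4.04e-12), the rhodopsin gene ninaE from 5989 to 3244 (log2 -0.72), CdsA from 223 to 93.0 (log2 -1.14), and Pdh rose from 107 to 177 (log2 0.95). Camera gave adjusted p = 0.651, adjusted p = 0.902 with an estimated correlation, and fry 0.046, with a median of -0.04. On the deposited scale, which fry used, the retina median was -0.20. Muscle markers gave 1 up and 5 down of 15, or 0 and 5 without per0 CT60 and CT68, with a median of 0.28, a mean of -0.18 and a downward camera test (adjusted p = 0.891): flightin (fln) fell from 9.26 to 4.0 RPKM (log2 -1.03), Act79B from 1.43 to 0.419 (log2 -1.48), Mf changed by -0.56, and TpnC4 had 231 reads in wildtype and 1 in per0 (ratio 267, 95% interval 47.5 to 10600). Fat body markers gave 2 up and 2 down of 12, with the storage protein genes Lsp2 at 157 ± 170 and 398 ± 398 RPKM (log2 2.76, adjusted p = 0.00407) and Lsp1beta at 0.745 and 2.42 (log2 1.48), and with fit at 663 and 306 and Pepck at 174 and 94.0 (log2 -0.91). Per0 CT60 and CT68 had fat body medians of 1.38 and 0.75 above the other per0 libraries. Cuticle and trachea markers gave 3 up and 1 down of 14 (adjusted p = 0.182 by camera, 0.788 with an estimated correlation and 0.017 by fry), with Cpr72Ec from 4.04 to 19.3 RPKM (log2 2.47), Cpr49Ag at 1.65, dusky (dy) at 1.75 and Cpr49Ae at -0.57. Hemocyte markers gave 1 up and 4 down of 9, with the phagocytic receptor eater from 3.91 to 1.45 RPKM (log2 -1.18), crq and Ppn down and srp up by 0.73.

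Glycolysis and sugar genes gave 1 up and 4 down of 12, 1 and 5 adjusted over the list alone, 2 and 3 after rescaling, and 1 and 8 without per0 CT60 and CT68, with Gapdh2 from 68.4 to 41.5 RPKM (log2 -0.56), Pglym78 from 7.65 to 17.8 (log2 1.22), Tps1 at -0.77 and PyK at -0.37; in per0 CT60 and CT68 the list had medians of 0.78 and 0.64 against the other per0 libraries. Lipid genes gave 0 up and 5 down of 11, 1 and 3 after rescaling, or 1 and 2 under quantile scaling, with the lipid droplet gene Lsd-1 from 64.3 to 36.0 RPKM (log2 -0.73), bgm at -0.77, Lip4 at -0.74 and CPTI at -0.29. The oxidative phosphorylation list gave 4 up and 6 down of 22, 4 and 8 adjusted over the list alone, 6 and 5 after rescaling, and 5 and 11 without per0 CT60 and CT68. Its 17 members on nuclear chromosomes gave 1 up and 6 down, and 1 and 11 without those libraries: sun fell from 29.2 to 15.4 RPKM (log2 -0.75), ND42 rose from 13.3 to 22.0 (log2 0.88), levy stood at -0.48 and ATPsyn-Cf6 at -0.28. The other 5 lie on the mitochondrial chromosome, of which 3 rose, chosen here after their values were seen: ND4 (log2 1.40, adjusted p = 0.000563), ND4L (1.70, 0.00566) and ND1 (0.98, 0.0168). Of the separate list of 14 mitochondrially encoded genes 1 passed, mt:tRNA:S:UCN, at 2.20 and 4.13 RPKM (log2 2.39, adjusted p = 0.0261), and 0 adjusted over the list alone. In all 25 tested genes of that chromosome, 4 rose and 0 fell, and without per0 CT60 and CT68, where mt:lrRNA was low, 12 rose and 0 fell. Of the 24 lists, camera called 2 (core clock and ribosomal proteins), camera with an estimated correlation 0, and fry 7. The fry count includes the downward offset of the median gene on the deposited scale.

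Rhythms in wildtype brains were sought as a 24 h cycle across both days. tim cycled 2.98-fold from trough to peak, with its peak at 12.7 h after subjective dawn (adjusted p = 0.00906), from 20.8 RPKM at CT24 to 90.8 at CT36. Pdp1 cycled 2.03-fold with its peak at 11.9 h (adjusted p = 0.0371). Ugt35b (3R:6994215-6995968), a glucuronosyltransferase gene, peaked near dawn, at 0.478 h, with 3.14-fold cycling (adjusted p = 0.00543), and its values ran from 6.91 RPKM at CT64 to 31.7 at CT24 in wildtype and from 9.16 to 15.3 in per0. CG11407 cycled 3.46-fold with its peak at 20.8 h (adjusted p = 0.00543), CG14329 7.62-fold at 1.31 h (0.00906), CG17386 5.04-fold at 15.5 h (0.0217) and CG5535, which encodes a predicted amino acid transporter, 3.57-fold at 12.9 h (0.0323).

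The other core clock genes did not pass over all genes: per (2.96-fold, peak 9.89 h) and vri (2.45-fold, 11.1 h) each had adjusted p = 0.143, and Clk (2.15-fold, 21.1 h) had 0.333. cwo, cry and cyc had adjusted p of 0.771, 0.970 and 1. Also among the 12 smallest p values without passing were CG31300 (adjusted p = 0.0876), CG4908 (0.103), CG10553 (0.136) and CG17646 (0.143). Adjusted over the list alone, 6 of 8 core clock genes passed (tim, Pdp1, per, vri, Clk and cwo).

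In all, 7 of 10423 genes passed (limma), with 549 at unadjusted p under 0.05 where 521 arise by chance. The count was 0 with a Kendall rank test (572 unadjusted), 0 with wildtype fitted alone (703 unadjusted), 0 at periods of 20 h (393) and 28 h (683), and 27 of 32964 with every transcript tested. Left out in turn, single libraries gave 3 to 9 genes: 3 without wildtype CT24 or CT36, 4 without CT40 or CT48, and 9 without CT52 or CT68. Ugt35b and CG11407 passed with every library left out, tim in 21 of 24 cases (adjusted p = 0.057 at the highest), CG14329 in 22, CG17386 in 19, CG5535 in 12 and Pdp1 in 8. Without per0 CT60 and CT68, which enter through the shared spread, 13 passed, per among them. With edgeR on the recovered reads tim, Ugt35b, CG11407, CG14329, CG17386, CG5535 and CG31300 passed, and Pdp1 did not.

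**Figure D3:**
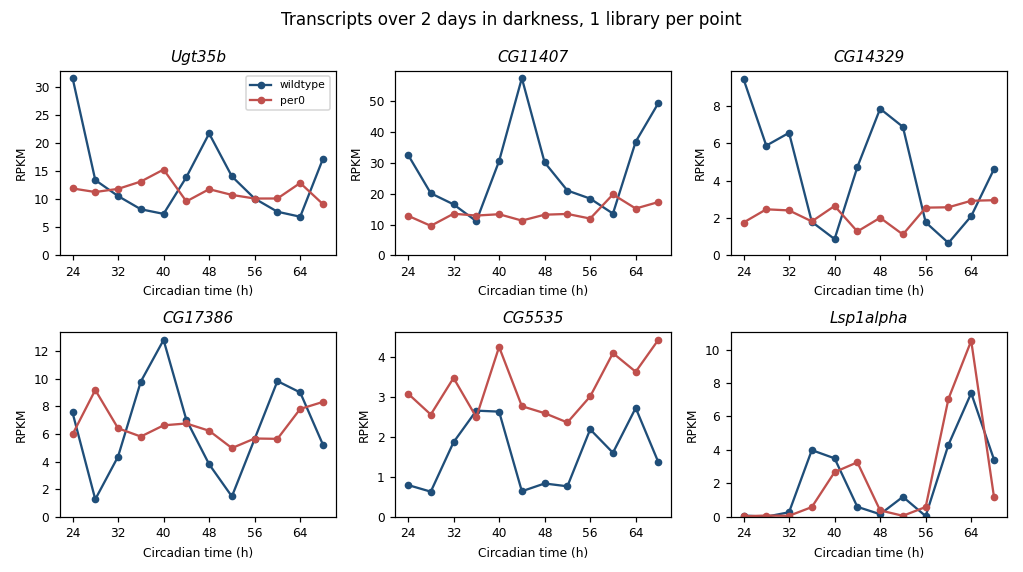
RPKM (vertical) of 6 transcripts against circadian time in hours (horizontal), with 1 library per point and lines joining the libraries of a genotype. Wildtype Ugt35b runs from 6.91 to 31.7 RPKM and per0 from 9.16 to 15.3, whereas Lsp1alpha, a fat body gene, has its fitted peak at 15.3 h in wildtype and 15.8 h in per0.

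By list, rhythmic members (unadjusted p under 0.05) were more frequent than elsewhere in 4 of 24 lists. In the core clock list these were 6 of 8 (Fisher's exact test, adjusted p = 1.28e-05). Outputs known from fly heads had 7 of 17, Ugt35b, CG17386, CG10553, CG10513, Pdh, Slob and CG5798 (adjusted p = 1.59e-04), and all 7 passed adjusted over the list alone. Fat body markers had 5 of 12, the storage protein genes Lsp1alpha, Lsp1beta and Lsp2 with Obp99a and Tsf1 (adjusted p = 0.00185), also 5 adjusted over the list alone. Fisher's test treats members as independent, but these 12 moved together over libraries (mean pairwise correlation 0.607). The list p value is thus likely too small, and 1 shared fluctuation could make several members pass. In per0 too, Lsp1alpha (0.00013) and Lsp1beta (0.000292) had unadjusted p under 0.01 by limma. Activity-dependent early genes had 4 of 10, CG14186, Hr38, sr and puc (adjusted p = 0.00743; 1 adjusted over the list alone), and adjusted p = 0.587 when members at p under 0.01 were counted.

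Detoxification genes had 4 of 27 (adjusted p = 0.153; 0.00469 with members at p under 0.01; 3 adjusted over the list alone). Antimicrobial genes had 4 of 22 (adjusted p = 0.104), of which Drs passed adjusted over the list alone, cuticle markers 3 of 14 (0.117; 1 adjusted over the list alone), neuropeptides 3 of 25 (0.341), snoRNAs 17 of 226 (0.341), and ribosomal proteins 0 of 79 (0.104). Retina (Pdh), muscle (TpnC73F), receptor (Oamb), heat shock (Hsp67Bc) and glycolysis (Tpi) lists had 1 each. Clock kinase, hemocyte, glia, neuron, mitochondrial, oxidative phosphorylation, spliceosome, lipid and sleep lists had 0. Lists given here without such a count had 0 genes that passed adjusted over the list alone.

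In per0 the same fit asked whether any cycle remained without Period. The smallest p values belonged to ImpL2, which encodes an inhibitor of insulin signalling (p = 9.54e-05, adjusted p = 0.676, peak 16.8 h), and to the storage protein genes Lsp1alpha (p = 0.00013, adjusted p = 0.676) and Lsp1beta (p = 0.000292, adjusted p = 0.977). CG4476, CG32196, CG13360, CG10962, CG15117, CG11501 and nc_21305 came next. Among core clock genes Clk had the smallest p (0.0485, adjusted p = 0.999), 0 passed adjusted over the list alone, and tim ranged from 111 to 166 RPKM. Of the fat body list 4 genes passed adjusted over the list alone, Lsp1alpha, Lsp1beta, Pepck and fit, and without CT60 and CT68 the 2 storage protein genes did. Over all genes 0 passed (limma, 291 at unadjusted p under 0.05), 0 with a Kendall rank test (239) and 0 with edgeR (308). By chance 521 would arise, so the test may be conservative here, and 0 calls are weak evidence that no rhythm remained. Without CT60 and CT68 there was 1, Rgk2, chosen here after its values were seen.

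The difference in rhythm between genotypes was tested directly. Among the core clock genes 4 differed adjusted over the list alone: tim (adjusted p over the list = 0.00418), vri (0.00947), Pdp1 (0.0115) and per (0.0115), while Clk, cwo, cry and cyc did not. Among outputs 3 did, Ugt35b (0.000503), CG17386 (0.00932) and CG10513 (0.0266). Ugt35b (0.000799) and the antifungal peptide gene Drs (0.016) were the only members past the threshold adjusted over the detoxification and the antimicrobial list alone. Over all genes the smallest values were Ugt35b (p = 2.96e-05) and CG14329 (p = 4.52e-05), both with adjusted p = 0.236, followed by CG11407 and CG17646 (both 0.324), CG4908 (0.610), CG17361 and tim (both 0.778), and Drs, nc_19632 and Cyp4s3 (each 0.860). None of 10423 genes passed (limma, 313 at unadjusted p under 0.05, where 521 arise by chance). edgeR called 1, Ugt35b (adjusted p = 0.0403, 322 unadjusted), the fit without per0 CT60 and CT68 called Rgk2, and leaving out wildtype CT32 let CG14329 pass (adjusted p = 0.0315).

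Between the first and second day in darkness 0 genes passed (limma, 793 at unadjusted p under 0.05, where 521 arise by chance, smallest adjusted p = 0.648), and edgeR also called 0 (709 unadjusted). Per0 CT60 and CT68, which stood apart from all other libraries, both fall on the second day and so enter the day term. The excess over 521 need not reflect time in darkness.

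Splice junction usage differed between genotypes, with a near complete switch at Gprk2. Gprk2, a kinase of G protein-coupled receptors, used 3R:27236124-27259180 at 93.8% ± 3.36 in wildtype and 4.31% ± 4.94 in per0 (SD, n = 12), against 6.19% and 95.6% for the annotated 27231679-27259180 (adjusted p = 9.12e-14). In Roughened, which encodes a Rap1 GTPase, the annotated junction 3L:1861677-1862060 went from 99.7% ± 0.265 to 49.2% ± 3.03 (20024 and 21909 site reads; adjusted p = 3.4e-21), with the remainder at an unannotated end at 1862064. An unannotated junction at 3L:2697461-2697695 went from 0.0363% to 32.8% ± 3.30, and CG42351 used 2R:14645483-14645535 at 59.0% ± 10.6 and 5.91% ± 1.84. At the receptor tyrosine phosphatase gene Lar, reads spanning the gap 2L:19718547-19718574 made up 98.7% ± 4.95 of the site in wildtype and 0% in per0 (SD, n = 12; 157 and 925 site reads; adjusted p = 3.79e-22), and the gap ending at 19718581 rose from 0.637% to 99.7%. These gaps of 28 and 35 nt are unannotated, and a gap that short in the alignment need not be an intron.

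Of 3489 junctions 641 differed (18.4%; 1023 at unadjusted p under 0.05), 322 with a higher and 319 with a lower share in per0, in 256 genes. A difference of at least 20 percentage points was seen at 173, and 436 were annotated. At sites without an unannotated gap under 50 nt, 636 of 3476 differed. When the most used junction of each site was left out, an alternative chosen after seeing the data, 338 of 1892 differed, in which a pair of complementary shares counts once.

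No junction passed for a 24 h rhythm in wildtype, with a median of 31 reads per site and library. The smallest p values were at ps, Lar, Caps (2 junctions), CG4407, CG1358, stan and Mbs, all with adjusted p = 0.445. The quasi-binomial test gave 0 calls (223 at unadjusted p under 0.05), and limma on arcsine shares gave 0 (164); leaving out wildtype CT24 gave 1.

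The position of the genotype-dependent genes was compared with that of per on the X. Within 2 Mb of per 104 of 310 tested genes differed (33.5%), against 38.8% elsewhere (two-sided Fisher's exact test, p = 0.0664). On the X 35.4% differed, against 39.0% on the autosomes (p = 0.00529). By direction, 256 of 1697 X genes rose and 345 fell. On each of 2L, 2R, 3L and 3R, with 1886 to 2403 tested genes, 200 to 236 rose and 539 to 660 fell. The X median lay at 0.07 (log2) relative to the median gene. Calls used the deposited scale with its downward offset, so the lower share on the X need not mean smaller effects there.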

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

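Tests chosen after the result was seen were those of scaling for the genotype effect, of depth and time of day for per0 CT60 and CT68, of a clock-driven rhythm for the fat body genes, and of random orders for the introns; the others were set down before. A difference in rhythm between genotypes, tested directly and adjusted over the list alone, drew attention to tim (0.00418), vri (0.00947), Pdp1 (0.0115), per (0.0115), CG17386 (0.00932), CG10513 (0.0266) and Ugt35b (0.000503 among outputs, 0.000799 among detoxification genes), and to Drs (0.016) among immune genes. Outside the main measurement, a signal appeared in introns, where 18.1% of the genes with an unadjusted exon p under 0.01 had an unadjusted intron p under 0.05 and 0 of 6760 genes passed, a share reached by 37 of 100 orders of the time points, and in short gaps within reads, 117 of which were found on autosomes in 1 genotype alone.

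The breadth of the genotype effect may have a source other than Period. Random splits of the 24 libraries, 99 of them with the real one making 100, gave at most 1 gene against 4024, so the real grouping ranked 1. Scaling by a few abundant RNAs could not account for most calls, since 75.42% kept their sign and call under median-of-ratios scaling, and background confined to the neighbourhood of per is unlikely, since 33.55% of genes there were called, fewer than elsewhere. A candidate explanation is a difference in genetic background between the stocks on all chromosomes: unannotated gaps under 50 nt, seen in at least 6 libraries of 1 genotype and 0 of the other in genes above 5 RPKM, numbered 117 on autosomes, against at most 6 in random splits. Such gaps may be small deletions. Calls in any gene, those of the clock included, could therefore stem from background, the loss of Period, or both, and nothing here separates these. No batch or date is labelled, so a technical difference between the libraries of the genotypes cannot be told apart either.

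Whether per0 CT60 and CT68 carry RNA of another tissue stays open. The highest of 5 tissue list medians in them, relative to the other 10 per0 libraries, was 1.10 for fat body markers, with CT68 alone at 0.75. Short and mitochondrial RNAs were also low there, which a tissue difference need not explain. On the same measure the mitochondrially encoded list stood at -2.81 and the snoRNA list at -1.02. What lowered these RNAs was not tested. They had the fewest reads of the per0 libraries, 9.61 and 8.38 M, but depth is an unlikely cause, since thinning the reads of the other 10 to the depth of CT68 closed at most 1.64% of the gap on the second component, in 20 draws. Time of day is also unlikely, as per0 CT36, at the phase of CT60, scored 24.5, within the range of the rest.

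Of 12 fat body markers 5 had a rhythm in wildtype and 4 in per0 adjusted over the list alone, and 0 over all genes. Of the 5, 2, Lsp1alpha and Lsp1beta, had a rhythm in per0 over the list alone without CT60 and CT68. A clock-driven rhythm that per0 abolishes in every rhythmic member would not give this. Both genes had low levels, with means of 2.14 and 1.58 RPKM over the 24 libraries, and belong to a list that moves together. A single shared fluctuation in per0 could thus make both pass, so such a clock-driven rhythm is not ruled out. For Lsp2, Obp99a and Tsf1 a clock-driven rhythm also stays open, as the smallest p of the difference in rhythm was 0.246 (limma). Varying carry-over of fat body with the dissected brains might account for these. Members moved together over the 24 libraries with a mean pairwise correlation of 0.607, where the 95th percentile of 1000 random gene sets was 0.101. That correlation cannot tell carry-over from joint regulation of these genes. The 5 had fitted peaks at 14.9 to 16.1 h in wildtype and at 15.5 to 16.3 h in per0. Those per0 peaks include CT60 and CT68, where fat body markers were raised. Without these libraries the per0 peaks lay at 16 to 17.4 h. Lsp2, Obp99a and Tsf1 then had unadjusted p of 0.135, 0.115 and 0.168 in per0 (limma). Members that move together get similar fitted peaks within a genotype from any shared fluctuation, timed or not. Similar peaks among the 5 therefore cannot tell carry-over from a rhythm. A shared systemic rhythm that does not need Period, such as one tied to feeding, would give the same pattern and was not tested.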

How the results depend on the processing

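Tests added after the data were seen were edgeR on recovered reads, the fits without per0 CT60 and CT68, the junction set without the most used junction of each site, and a junction dispersion not under 1. The genotype count stayed within 1.5 times under the other fixed settings (2710 at 5 RPKM to 4807 at a threshold of 0.1), and moved to 13265 with every transcript, where more features were tested, and to 1267 with the second day alone, against 2934 with the first. With libraries left out in turn it ran from 3740 to 4097. The wildtype rhythm count moved to 27 with every transcript, to 0 for wildtype fitted alone, 0 with the Kendall test, 0 at 20 h and 0 at 28 h, and to 13 without per0 CT60 and CT68, and ran from 3 to 9 with libraries left out. The per0 rhythm count was 1 without those libraries and 0 to 0 with libraries left out. The rhythm difference moved to 1 without them and to 1 with edgeR, with a range of 0 to 1, and the day effect had a range of 0 to 0. Junctions moved to 338 without the most used junction, where fewer were tested, with a range of 538 to 613, and the junction rhythm had a range of 0 to 1. Lists past the threshold moved from 2 to 0 with an estimated correlation and to 7 with fry, which asks another question and includes the offset of the median gene. For the other moves the cause was not tested.

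Of the named genes in the genotype effect, 4408 values kept their direction and side of the threshold, 62 were weaker, 18 stronger and 1 reversed: 5-HT2, at 0.0553 (log2, adjusted p = 0.747) on the second day alone, where the cause was not tested. In the wildtype rhythm 3981 were the same, 70 weaker and 14 stronger. DESeq2 was not run, as the table holds RPKM. With time point as a replicate block, which matches the genotypes in time, the count was 3971. The 2 libraries of a time point had correlations of -0.102 to 0.188, and 2 of 24 correlated best with their own. At a median of 31 reads per site and library, 70 of 100 simulated junction shifts of 0.2 between genotypes were recovered; junction rhythms were not simulated.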

Other observations

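The random orders for introns were a test chosen after the result was seen. In the intron values of the same table, of 94 genes with an unadjusted exon p under 0.01 in wildtype, where 67.6 arise by chance, 17 had an unadjusted intron p under 0.05 (18.1%), against 319 of 6666 other genes (4.79%). Of 100 orders of the wildtype time points, the real one included, 37 gave at least that share, with a median of 16% in random orders. In per0 it was 1 of 24 (4.17%). Among the core clock genes with tested introns, tim had p = 0.0012 (adjusted p = 0.623), with a peak at 11.4 h and 12.7 h in its exons. The others did not reach 0.05: Pdp1 (0.0568), cry (0.193), cyc (0.251), cwo (0.467), per (0.513) and Clk (0.905). Over all introns 0 of 6760 genes passed in wildtype (limma, 336 at unadjusted p under 0.05) and 3 in per0. The share therefore does not separate a daily change in transcription from variation between libraries that exons and introns of a gene have in common; reads of unspliced RNA and of mature RNA overlapping an intron were not separated.

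The short gaps found in 1 genotype alone numbered 133 of 9077 considered, 14 on the X and 117 on autosomes, with 25 on 2L, 24 on 2R, 30 on 3L, 37 on 3R and 1 on chromosome 4. A length that is not a multiple of 3 was seen in 79. The 28 nt gap in Lar is among them, with 155 reads over 12 wildtype libraries and 0 in per0.

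Random orders or splits were also run for the remaining comparisons. For the wildtype rhythm the real order ranked 1 of 100, with 7 genes against at most 2 in random orders. For the per0 rhythm, the difference in rhythm and the day effect the real labels gave 0 calls, and random orders or swaps at most 11, 1 and 1. Ties count against the real labels, so with 0 calls their rank of 100 of 100 was fixed in advance and says nothing. For junctions the real split ranked 1 of 50, with 641 against at most 2. The closest pair of libraries, per0 CT24 and CT36, had a correlation across genes of 0.959 and a chi-square of 30.1 per degree of freedom on recovered reads, more than counting error alone gives.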
